A study of Sus scrofa with 8 samples.

How the data were processed

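The series measured jejunal gene expression in 25-day-old piglets on 1-colour microarrays, with 4 suckling piglets and 4 piglets that had been weaned at 21 days of age. Per the labels' protocols, total RNA with an integrity number of at least 7.0 was amplified, labelled with the dye Cy3 and hybridised, with 1 piglet per array. Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7. The deposited scanner files give, per spot, a processed intensity from which the software had already subtracted background, a median spot intensity, a local background intensity and flags for outlier spots and for spots well above background. The deposited table of the whole series holds log2 values of the same arrays. Set against the scanner values, its columns had the order of each array's processed intensity and a common distribution, as after quantile normalisation, a step that no source used here states; the median of each of the 8 columns was 5.50, and whether they were shifted by a constant stays unknown.

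From the processed intensities, control spots were left out, spots flagged as outliers were set to missing and spots of one probe were averaged, which left 43603 probes. Each array was put on the log2 scale and its own 75th percentile was subtracted, so a value of 0 marks that percentile. A probe was tested when it was well above background on at least 4 arrays and had at least 3 values per group; 30554 probes were tested. The array names probes by transcript accessions, contigs or probe numbers. RefSeq accessions were looked up without versions in a gene table of the Sscrofa11.1 assembly, which was used for names alone. This gave 6924 probes a symbol, 15.9% of all probes and 85.6% of those with a RefSeq accession, for 3216 symbols. The remaining probes stayed unnamed here, including 13273 named by contigs and 6843 by Ensembl transcripts. The array number limits the precision, and 67.6% to 71.0% of probes were well above background per array.

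Weaned and suckling piglets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the sole term), and Benjamini-Hochberg adjusted p-values under 0.05 counted as past the threshold. For a gene with several probes, the brightest tested probe stood for it. For a gene not well above background on any array of a group, the fold is a lower bound. It sets the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own signal and the lowest signal among probes well above background. The genes named in the text follow a rule with 2 parts. The first part takes up to 10 genes with the largest rise and up to 10 with the largest fall among symbols past the threshold whose groups do not overlap, without LOC numbers. The second part takes, from each gene list past the list threshold, up to 4 members past the threshold, and up to 2 from every other list; a list with none names the member with the smallest p. There were 35 gene lists of digestive, metabolic, immune and cell type genes, holding 913 members, of which 453 were tested. Members were matched by exact symbol, 2 of them by a second symbol fixed with the lists. Lists with at least 5 tested genes, 31 in all, were tested with limma's cameraPR at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. A list score per array is the median over members of the log2 signal minus the member's mean over the arrays, and was compared by an exact two-sided permutation test over the 70 arrangements, whose smallest p is 0.0286.

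The tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were quantile normalisation, median scaling, normexp background correction with an offset of 50, other filters on dim probes, flagged spots kept, an intensity trend with a robust prior, array weights, the replicate number as a block, the deposited log2 table, a fold of at least 2, each array left out in turn, and the mean over a gene's probes. The normexp run used the median spot intensity, because the files used here hold no mean spot intensity. After seeing the data, 2 further choices were added. One was a normexp run with the array's median background at spots with a flagged background. The other applied the first part of the naming rule without suckling replicate 1, with the filter on dim probes applied again.

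On simulated data with the real probe means and the probe spreads as moderated by limma, 200 of 30554 probes were changed in each of 5 runs. Of the probes changed by 1 on the log2 scale 39.2% were recovered, and 92% of those changed by 2. The simulated values were independent normal draws without an outlying array, so the shares recovered hold for such data alone. Of all calls in these runs, 5.09% were false. In 20 simulated data sets without a group difference, 5.48% of lists had an unadjusted p under 0.05; the simulated genes were independent, so this does not cover lists whose members move together.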

Results

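Gene expression was measured in the middle jejunum, a stretch of the small intestine where most nutrients are absorbed, of piglets aged 25 days. The piglets came from 4 litters. One group of 4 stayed with the sow, and the other 4 had been weaned at 21 days onto a basal diet with 14.48 MJ/kg digestible energy and 20.50% crude protein, so they were sampled 4 days after weaning. Each array held the RNA of a 2 cm segment of the jejunal wall, a mixture of epithelium, immune cells, vessels, nerves and muscle. Per the labels, each treatment took 1 piglet from each litter, but no label ties a replicate number to a litter. The 75th percentile of the processed intensity was 244.0 in suckling replicate 1 and between 316 and 393 in the other 7 arrays. All suckling arrays lay on one slide and all weaned arrays on the other, with one scan each, so slide and group cannot be told apart in any comparison here. The median variation of repeated probes was 9.76% ± 1.00 (SD, n = 4) on the suckling slide and 7.27% ± 0.86 (SD, n = 4) on the weaned slide (exact two-sided permutation p = 0.0286, the smallest the design allows). The 100 brightest spots held 23.6% ± 2.40 and 21.1% ± 0.55 of the signal (SD, n = 4 per slide; exact two-sided permutation p = 0.0286), and the extraction software marked all 4 suckling arrays for evaluation and all 4 weaned arrays as in range.

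The comparison asks which jejunal transcripts differ between suckling piglets and piglets weaned 4 days earlier. Of the 2 named genes past the threshold, CYP1A1, a cytochrome P450 that oxidises planar aromatic compounds, rose more. It was not well above background on any suckling array and was well above background on all 4 weaned arrays. Its level was at least 15.9-fold higher in weaned piglets (limma adjusted p = 0.0186). The measured means were -5.96 ± 0.74 in suckling and -1.47 ± 1.07 in weaned piglets (log2, SD, n = 4 per group). PGA5, which encodes a pepsinogen, rose 2.39-fold, by 1.25 on the log2 scale (SE 0.18, limma adjusted p = 0.0425). Its 6 probes did not move together, with log2 differences from -2.14 to 2.39 and 1 probe past the threshold, and pepsinogens form a family of similar genes, so the PGA5 value is uncertain. In all, 54 of 30554 tested probes passed the threshold, 53 higher and 1 lower in weaned piglets, and the 2 named genes were the ones past it among 2813 tested.

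Most of the 54 probes, 49, have no gene symbol here. The 2 that rose with the smallest p were A_72_P174656 (contig TC625654), higher by 2.21 (SE 0.15, limma adjusted p = 0.00193), and A_72_P328523 (accession AJ649856), higher by 1.96 (SE 0.14, limma adjusted p = 0.00193). The single probe that fell was A_72_P266707 (contig TC565888), which fell by 2.85 on the log2 scale (SE 0.22, limma adjusted p = 0.00262) and was well above background on 4 suckling arrays but on 1 of 4 weaned arrays. At an unadjusted p under 0.05 by limma there were 3763 probes, where 1527.7 are expected on average without a group difference. Probes are not independent, so such a count can lie far from this average by chance. Slide and group also coincide, so the excess alone does not show an effect of weaning. The count of 54 fell to between 9 and 25 without suckling replicate 2 or 3 or any 1 weaned replicate, was 40 without suckling replicate 4 and grew to 554 without suckling replicate 1. The CYP1A1 call was lost without suckling replicate 2 or 3 (limma adjusted p = 0.0533 and 0.0534), and without any 1 weaned replicate the gene no longer met the filter on dim probes. It was also lost under both normexp runs, where the log2 difference was 0.97 and 1.41. The PGA5 call was lost without suckling replicate 2 or 3 and without each weaned replicate (limma adjusted p = 0.0917 to 0.212). It was also lost under quantile normalisation, median scaling, the deposited log2 table and no filter on dim probes (limma adjusted p = 0.0527 to 0.08), under the planned normexp run, and with the mean over its probes, where the log2 difference was 0.77 (limma adjusted p = 0.141).

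**Figure D1:**
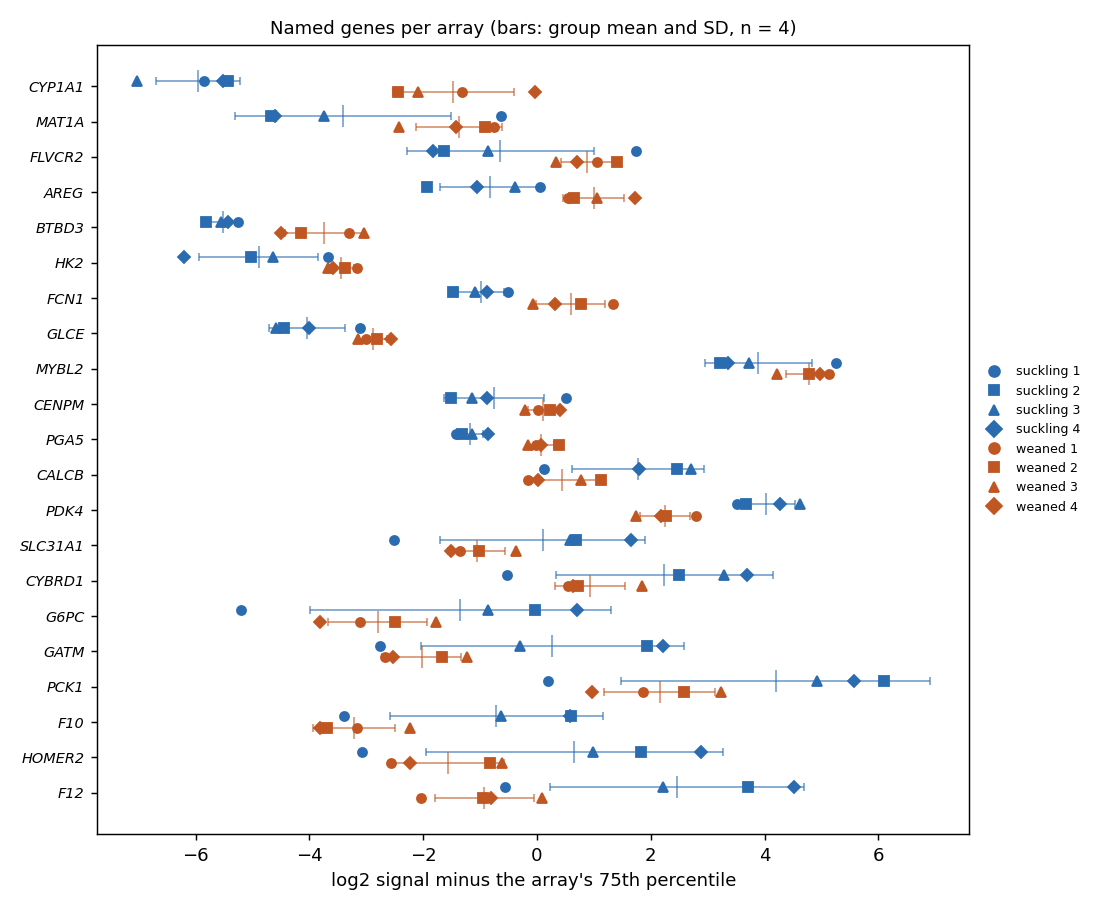
Signal of the genes with the largest changes, with the log2 signal relative to the array's 75th percentile on the horizontal axis, 1 point per array and bars for group mean and SD (n = 4). The suckling points of CYP1A1 lie around -5.96 and its weaned points around -1.47, and suckling replicate 1 (blue circle) lies apart from the other suckling points for genes such as PCK1, F12 and G6PC. Naming genes without that array favours genes in which it lies apart, so its place here is partly set by the choice.

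Of the 31 gene lists tested, 7 were shifted relative to the other genes, 4 upward and 3 downward in weaned piglets, and in none of these 7 did a single member pass the threshold over all tested probes. When the arrays were regrouped, 16 of 35 splits, the labelled one included, gave at least 7 lists, so chance is not excluded for this count. The interferon response, genes that cells switch on against viruses, stood highest: 28 of its 30 tested members had a higher mean in weaned piglets, with a median log2 difference of 0.86 (cameraPR adjusted p = 5.45e-05; adjusted p = 0.861 with an estimated correlation). Its member IRF9, a transcription factor of the interferon pathway, had 2.37 ± 0.30 in suckling and 3.06 ± 0.07 in weaned piglets (log2, SD, n = 4 per group). None of its members passed adjusted over the list alone. Its score was -1.51 and -1.13 in suckling replicates 2 and 4, but 0.14 and 0.69 in suckling replicates 1 and 3, against 0.22 to 0.46 in the 4 weaned arrays (exact two-sided permutation p = 0.286). Without suckling replicate 2 the median log2 difference of the list was 0.49.

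Inflammatory mediators were shifted upward, with 33 of 44 members higher and a median of 0.27 (cameraPR adjusted p = 0.00512; adjusted p = 0.788 with an estimated correlation); 3 members were higher adjusted over the list alone. NOS2, the inducible nitric oxide synthase, had the smallest p among them, at 0.08 ± 1.09 in suckling and 2.71 ± 0.75 in weaned piglets (log2, SD, n = 4 per group), with a limma adjusted p of 0.140. Genes of macrophages, dendritic cells and neutrophils had 14 of 16 members higher and a median of 0.30 (cameraPR adjusted p = 0.0448; adjusted p = 0.995 with an estimated correlation), with none past the threshold adjusted over the list alone. FCER1G, a signalling chain of Fc receptors, was 2.32 ± 0.14 in suckling and 3.09 ± 0.49 in weaned piglets. Cell cycle and DNA replication genes had 10 of 11 members higher and a median of 0.60 (cameraPR adjusted p = 0.0289; adjusted p = 0.995 with an estimated correlation), again with none adjusted over the list alone. CCNB1, a mitotic cyclin, was 1.76 ± 0.78 in suckling and 2.55 ± 0.47 in weaned piglets. The call of inflammatory mediators was lost without suckling replicate 2 or weaned replicate 1 (cameraPR adjusted p = 0.0635 and 0.0525), and that of the macrophage list without suckling replicate 1, 2 or 4 or weaned replicate 1 or 2 (0.0702 to 0.363). The cell cycle call was lost without suckling replicate 2 or 4 or weaned replicate 1 or 4 (cameraPR adjusted p = 0.0694 to 0.392), and its median was 0.995 without suckling replicate 1. Without weaned replicate 3 the medians of inflammatory mediators and of the macrophage list were 0.46 and 0.51.

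Fibroblast and extracellular matrix genes were shifted downward, with 12 of 13 members lower and a median of -0.34 (cameraPR adjusted p = 8.64e-05; adjusted p = 0.293 with an estimated correlation); 2 members were lower adjusted over the list alone. CTGF, a matrix-associated growth factor, was -1.26 ± 0.49 in suckling and -2.29 ± 0.28 in weaned piglets (log2, SD, n = 4 per group). Gut hormones of enteroendocrine cells had 8 of 12 members lower and a median of -0.09 (cameraPR adjusted p = 0.0176; adjusted p = 0.788 with an estimated correlation), with 2 lower adjusted over the list alone. The median of the hormone list was -0.27 without suckling replicate 1 and -0.19 without weaned replicate 3. CHGB, a protein of hormone-storing granules, was 1.62 ± 0.27 in suckling and 0.67 ± 0.33 in weaned piglets, and all 15 of its probes pointed the same way. Endothelium was the 1 list that also passed with an estimated correlation (adjusted p = 0.00283): 6 of its 9 members were lower, with a median of -0.34 (cameraPR adjusted p = 0.0289) and none past the threshold adjusted over the list alone. The estimated correlation of this list was -0.06, below the preset 0.01, so for this list the test with the estimate was the more lenient one. CDH5, the cadherin of vessel walls, was 0.97 ± 0.18 in suckling and 0.57 ± 0.14 in weaned piglets. The score of this list did not overlap between the groups (exact two-sided permutation p = 0.0286, adjusted p = 0.886 over the lists). The endothelium call was lost without suckling replicate 1 or 2 or weaned replicate 3 or 4 (cameraPR adjusted p = 0.0556 to 0.124), and the hormone call without suckling replicate 2 or weaned replicate 4 (0.141 and 0.0616); by fry none of the 31 lists passed.

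**Figure D2:**
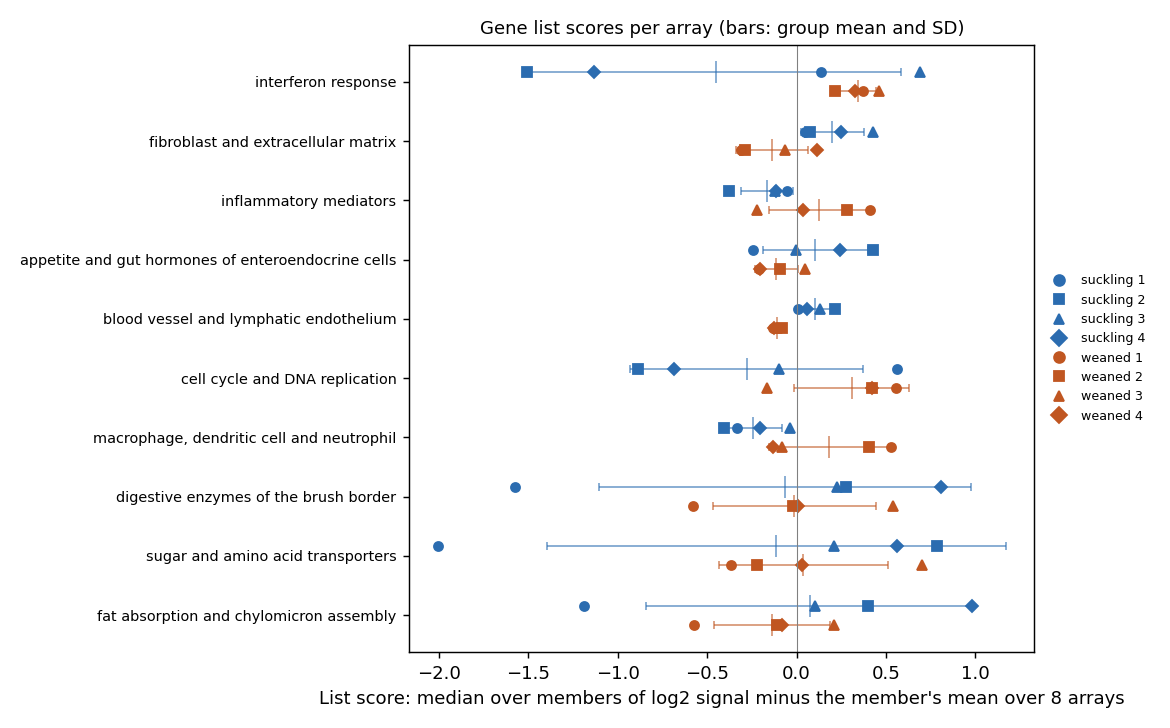
Score of 10 gene lists in each array, on the horizontal axis as the median over members of the log2 signal minus the member's mean over the 8 arrays, with 1 point per array and bars for group mean and SD. Suckling replicate 1 (blue circle) lies lowest for the 3 bottom lists, at -1.57, -2.01 and -1.19, while the suckling and weaned points of the endothelium list do not overlap.

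Brush border enzymes and nutrient transporters, which finish digestion and take up sugars and amino acids, did not pass the list test between the groups. The medians of these 2 lists were 0.04 and 0.23, with cameraPR adjusted p-values of 0.933 and 0.991; the test pointed downward in both although median and mean were above 0. Without suckling replicate 1 both medians turned, to -0.30 and -0.48 (cameraPR adjusted p = 0.150 and 0.310), and without weaned replicate 3 they were -0.06 and 0.03. Without suckling replicates 2, 3 and 4 the brush border median was 0.23, 0.06 and 0.36, and without weaned replicates 1 and 2 it was 0.18 and 0.09. Fat absorption and chylomicron assembly had a median of -0.22 (cameraPR adjusted p = 0.134). This list passed without suckling replicate 1, with a median of -0.73 (cameraPR adjusted p = 0.000482; adjusted p = 0.318 with an estimated correlation), and its median turned to 0.07 without suckling replicate 4; it was -0.07 and -0.33 without weaned replicates 1 and 3. APOC3, an apolipoprotein of chylomicrons, was 8.03 ± 2.48 in suckling and 5.54 ± 1.59 in weaned piglets (log2, SD, n = 4 per group), 5.59-fold lower, and 13.1-fold lower without suckling replicate 1 (limma adjusted p = 0.449 and 0.0535). Suckling replicate 1 had low values in these 3 lists: 26 of their 32 tested members were below all other suckling arrays there, and 23 were below all 4 weaned arrays. The housekeeping list had a median of 0.12 (cameraPR adjusted p = 0.816), and of 0.20, 0.06 and 0.07 without suckling replicates 1, 3 and 4. Of the other lists that did not pass, tight and adherens junctions passed without suckling replicate 1 (median -0.27, cameraPR adjusted p = 0.0194), oxidative phosphorylation without suckling replicate 4 (0.28, 0.00514), smooth muscle without weaned replicate 2 (0.45, 0.0271) and T and NK lymphocytes without weaned replicate 4 (0.39, 0.0486). All 4 of these calls were lost with an estimated correlation (adjusted p = 0.318, 0.910, 0.979 and 0.728 with an estimated correlation, in this order).

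Suckling replicate 1 lay apart from its group, and the planned run without it was therefore singled out, a choice made after seeing the data. In that run PCK1, the enzyme that commits carbon to gluconeogenesis, fell by 3.37 on the log2 scale in weaned piglets (SE 0.52, limma adjusted p = 0.0342). G6PC, which releases free glucose, fell by 2.73 (SE 0.51, limma adjusted p = 0.046). The coagulation factors F12 and F10 fell by 4.40 and 3.40 (limma adjusted p = 0.0277 and 0.0254), and GATM, the first enzyme of creatine synthesis, fell by 3.31 (limma adjusted p = 0.046). CYBRD1, an iron reductase of the brush border, and SLC31A1, a copper transporter, fell by 2.22 and 2.03 (limma adjusted p = 0.04 and 0.0373). PDK4, a kinase that restrains glucose oxidation, fell by 1.94 (SE 0.30, limma adjusted p = 0.0342), and its 9 probes all pointed downward. HOMER2, a scaffold protein, and CALCB, a neuropeptide gene, fell by 3.47 and 1.88, but the 2 CALCB probes differed in direction.

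In the same 7 arrays, CYP1A1 was at least 16.5-fold higher in weaned piglets (limma adjusted p = 0.0265) and MAT1A, which makes the methyl donor S-adenosylmethionine, rose by 2.96 (SE 0.42, limma adjusted p = 0.0285). AREG, an epidermal growth factor receptor ligand, rose by 2.12, HK2, a hexokinase of glycolysis, by 1.84, and FCN1, a ficolin of innate immunity, by 1.74. FLVCR2 rose by 2.32, BTBD3 by 1.87 and GLCE by 1.46; HK2 and BTBD3 were well above background on 2 of these 3 suckling arrays. The limma adjusted p of these 6 genes lay between 0.0265 and 0.047. MYBL2, a transcription factor of dividing cells, and CENPM, a centromere protein, rose by 1.35 and 1.28 (limma adjusted p = 0.0416 and 0.0348). Without suckling replicate 1, 554 of 30344 probes passed, 376 higher and 178 lower in weaned piglets, among them all 54 probes of the 8-array comparison, and 47 genes with a symbol passed, 2 of them under LOC numbers. With all 8 arrays none of these named genes except CYP1A1 and PGA5 passed; PCK1, for example, then had a log2 difference of -2.03 (SE 1.18, limma adjusted p = 0.528).

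**Figure D3:**
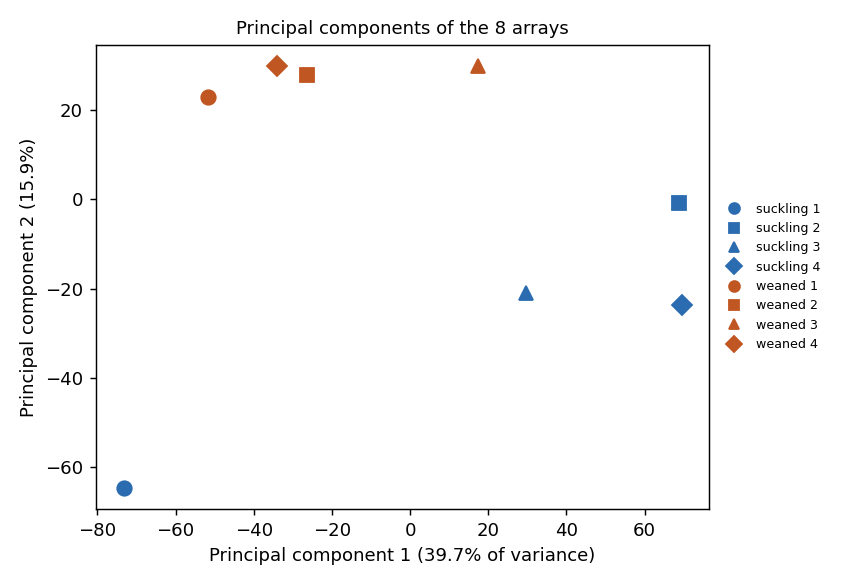
Positions of the 8 arrays on the first principal component (horizontal, 39.7% of variance) and the second (vertical, 15.9%), computed over 30520 probes. Suckling replicate 1 lies at -73.28 on the first component, on the side of most weaned arrays, while weaned replicate 3 lies at 17.4 beside suckling replicate 3 at 29.58. On the second component the groups, and so the slides, do not overlap. The suckling arrays lie at -64.67 (replicate 1) to -0.83 there, and the weaned arrays at 22.9 to 29.85, with weaned replicate 3 at 29.72.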

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

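Of the tests in this part, those of weak labelling, of a loss of villus epithelium and of exchanged arrays were chosen only after the result was seen. The test of a wrong label was set before the positions were computed, but after the similarity of the arrays was known; the arrays were ranked on the 500 probes with the lowest p because fewer than 20 probes passed with some arrays held out. In 174 groups of 4 values, 9 had a sample far from the other 3, where chance gives about 8.7 for independent normal values. The groups hold genes named by their p-values, some in the run without suckling replicate 1, and list scores of the same arrays. The figure of 8.7 therefore does not tell whether 9 is usual for such groups. The measure is the gap to the nearest sample divided by the range.

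Suckling replicate 1 was the outlying sample in 3 of the 9. It was lowest for APOC3 (0.857) and for the tight and adherens junction list (0.83), and highest for CDCA7 (0.91), a gene of proliferating crypt cells. Suckling replicate 3 was highest for XPNPEP2 (0.835), a brush border peptidase, and for NOS2 (0.9). Weaned replicate 1 was highest for IDH2 (0.888) and CD79A (0.981) and had the lowest 75th percentile of its group (0.905). Weaned replicate 3 was highest for CYBRD1 (0.862).

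Suckling replicate 1 correlated best with weaned replicate 1 (r = 0.978 across probes, which are not independent), and weaned replicate 3 best with suckling replicate 3 (r = 0.9829). In both pairs the arrays share a replicate number and a position on their slides, which coincide for all arrays. Deviations from the group mean correlated across probes at 0.368 for number 1 and 0.186 for number 3. For numbers 2 and 4 the correlations were 0.008 and -0.018. An effect of number or position therefore stays open, and these 2 cannot be told apart. Weak labelling of suckling replicate 1 as the whole cause could not be decided. Members of the 3 absorptive lists were lower in this array than genes of the same brightness. These lists, however, had the lowest medians of the 31 lists there (-2.525, -2.11 and -1.779 against the other suckling arrays). The test was chosen after the result was seen, so it was bound to find them lower. The median difference from genes of the same brightness was -2.04 (95% bootstrap interval over genes -2.44 to -1.45). Members of a list can move together, and the interval covers genes within this array, not piglets. This array also had the highest scaled spike-in signal (5.38 against 4.46 to 4.76 in the others) and the highest variation of repeated probes (10.9%). A lower yield of labelled RNA therefore stays open, as the whole cause or a part of it. A loss of villus epithelium as the whole cause could not be decided. Other cell types did not rise alike. Against the other suckling arrays the smooth muscle list was at -0.45 and the T and NK lymphocyte list at 0.47. Their difference was 0.92 (interval over genes 0.45 to 1.29). The smooth muscle score was -0.35 in suckling replicate 1, but also -0.30 in suckling replicate 4, and 0.61 in suckling replicate 3. The contrast thus depends on the arrays it is set against. The interval of the lymphocyte list reached -0.001, and the enterocyte identity list was at -0.152 (interval over genes -0.354 to 0.435). A change in lymphocytes, or a higher share of dividing crypt cells, stays open (cell cycle list at 1.18, interval over genes 0.83 to 1.60). A weaned piglet under a suckling label may account for part of the pattern, since this array lay at 0.77 between the suckling mean (0) and the weaned mean (1) on probes ranked without it, above weaned replicate 3 at 0.489, with 0.61 on the probes called higher in weaned piglets without it and 1.10 on those called lower; but suckling replicate 3 reached 0.54, so the measure separates the groups poorly, and CYP1A1 was not well above background in suckling replicate 1. An exchange with weaned replicate 3 may be a candidate explanation as well: that split called 1427 probes, against 54 for the labelled split and at most 3 in the remaining 33. The 54 that follow the labels speak against it unless they come from the slide. The second principal component (15.9% of variance) also followed the labels, or the slide. Suckling arrays lay there at -64.67 to -0.83, with suckling replicate 1 lowest, and weaned arrays at 22.9 to 29.85, with weaned replicate 3 at 29.72. A wrong label, an exchange and a real difference between piglets therefore cannot be told apart here.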

How the results depend on the processing

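Counts are probes past the threshold, then higher and lower in weaned piglets, against 54, 53 and 1. Normexp gave 0, 0 and 0 (250 probes at an unadjusted p under 0.05 by limma), shifted the median log2 difference of all probes to -0.10, and turned CD79A to -0.0167 and HK2 to -0.0544. In suckling replicate 4 and weaned replicate 1, signal minus local background reached -61216.5 and -11649.0 at single spots. An effect of these spots alone on the correction was not tested. With the array background at flagged spots, chosen after seeing the data, the counts were 56, 53 and 3, with 26 probes shared. Array weights gave 89 in all and 10 lower, with all 54 probes shared; the cause was not tested. Lower probes numbered 4 under quantile normalisation, 2 without the filter, 3 with a trend and robust prior and 5 in the deposited table; the cause was not tested. The replicate block, which leaves fewer residual degrees of freedom, gave 0, 0 and 0 (4193 probes at an unadjusted p under 0.05). With it, CYP1A1 and PGA5 had a limma adjusted p of 0.0547 and 0.161. Whether the numbers pair the samples stays open: 2 of 4 pairs had a correlation of deviations over 0.1, and 3 of 8 arrays correlated best with their own number. Leaving out each array gave 9 to 554, with 8 to 376 higher and 1 to 178 lower, and 2 to 7 gene lists against 7. The lists numbered 1 with an estimated correlation, 0 by fry and 4 with the mean over probes. Of 1084 gene values under alternatives, 1042 kept direction and side of the threshold, 18 lost and 22 gained the call. These values cover 52 genes, of which only CYP1A1 and PGA5 were past the threshold and could lose a call. All 18 losses were theirs, so the 1042 mostly count genes without a call to lose. CYP1A1 also dropped out of the test where it failed the filter on dim probes. Of 154 values of the 7 lists past the threshold, 116 kept both, 38 lost the call and 0 turned direction. The slide block was not run, since slide equals group. Dim genes such as CYP1A1 are limited by signal over background.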

Other observations

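The tests of the other CYP1A1 probe and of the spike-ins without suckling replicate 1 were chosen after the result was seen, and the run without that array, one of the planned runs that leave out each array, was singled out then. Without that array, cell cycle and DNA replication genes were higher in weaned piglets by a median of 0.995 (cameraPR adjusted p = 2.93e-05; adjusted p = 0.318 with an estimated correlation), and 10 of 11 members passed adjusted over the list alone. MCM3, a part of the replicative helicase, rose by 1.04 (limma adjusted p = 0.0348), and PRIM1, a DNA primase subunit, rose by 1.04 (limma adjusted p = 0.0342). The fat absorption list had a median of -0.73 (cameraPR adjusted p = 0.000482; adjusted p = 0.318 with an estimated correlation), with 6 of 14 members lower adjusted over the list alone. The tight and adherens junction list had a median of -0.27 (cameraPR adjusted p = 0.0194; adjusted p = 0.318 with an estimated correlation). MCM3 and PRIM1 were chosen after their values were seen.

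The higher CYP1A1 signal does not come from a single faulty probe, since the other CYP1A1 probe, also not well above background on any suckling array, was at least 4.74-fold higher in weaned piglets (limma adjusted p = 0.0295; the measured difference of 3.93 in log2 is not its size). CYP1A1 is a classic target of the aryl hydrocarbon receptor, and activation of that receptor may be a candidate explanation. Of 7 other targets sought, 1 was tested, NQO1, with a log2 difference of 0.24 (SE 0.37), so receptor activation and other causes cannot be told apart; slide and group coincide for this gene as for all others.

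Chance was examined by regrouping the arrays. With 8 arrays, 2 of 35 splits gave at least 54 probes, the labelled split and one with 1427, so chance is not excluded; the split with 1427 exchanges suckling replicate 1 and weaned replicate 3 and points to a structure of the samples. Without suckling replicate 1, 1 of 35 splits, the labelled one, gave 554 probes and the highest other gave 538. The split with 538 differs from the labelled one only by placing weaned replicate 3 with the suckling arrays, and the next highest gave 18. The count of 554 does not exclude chance, because this run was singled out after the arrays had been seen and the removal favours the labelled split. For the gene lists, 16 of 35 splits had at least 7 lists past the threshold and the highest other had 16, so chance is not excluded for the list count. The added spike-in RNA differed by -0.19 between weaned and suckling arrays after scaling (4.62 ± 0.13 and 4.82 ± 0.38, log2, SD, n = 4 per group; exact two-sided permutation p = 0.457). This came from suckling replicate 1, at 5.38; without it the difference was -0.01 (exact two-sided permutation p = 0.886).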
